A study of Bos taurus with 11 samples.

How the data were processed

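Total RNA from the endometrial biopsies of 11 cows was labelled with the dye Cy3, with spike-in RNA added before labelling, and hybridised to Agilent 1-colour bovine arrays, per the labels' protocols. Each cow was a separate animal with 1 array. Fluorescence intensity was extracted with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes, and the deposited scanner files hold 45220 spots each, with a processed signal, mean signal, local background and detection flags on a linear scale. The authors also deposited a table of log2 values. Set against the scanner files, these are log2 processed signals scaled to the 75th percentile of each array and centred on the median of each probe over the 11 arrays, over 43713 entries, with column medians from -0.08 to 0.09; its direction is that of the signal. Relative to fertile cow 2, the reference, 100% of its probes lay within 0.01 of the scanner file for every other array except fertile cow 1, at 17.0%. The median difference of each array was taken out first, so this check does not test the scaling. The deposited file of fertile cow 6 lacks its header and rounds its signals, and its column of gene names is out of register with its probes (2 names match), so that names were taken from the other files by probe. No columns of the table were left unmapped.

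Probes were named through the RefSeq accession of the array's annotation with a gene table of assembly ARS-UCD2.0, used for names only, since the array was annotated on another build; no coordinates are given. Of 43653 non-control probes, 20595 were named by accession, 10745 by a current symbol in the files and 376 by a unique older symbol, while 11937 kept the name in the files. Control spots and spots flagged as outliers for non-uniformity or population were left out, 1 to 156 spots an array, and no non-control spot was saturated. The processed signal was taken to log2, the 75th percentile of non-control spots of each array was subtracted, and spots of a probe were averaged. Probes well above background (a flag of the scanner software) on at least 5 of the 11 arrays, in whichever group, were tested: 31877 probes. Where a probe was not well above background on any array of a group, its fold is a bound: the mean of the bright group against the mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

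Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only) with Benjamini-Hochberg adjustment over the probes tested, at a threshold of 0.05. Gene lists were tested with camera, a preset inter-gene correlation of 0.01 and 1 probe for each of 18430 genes (the tested probe with the highest mean), adjusted over 23 lists with at least 5 tested members. The spread within groups and the share of probes detected were compared with exact permutation tests over all 462 splits. The genes named were set by a rule: in each direction the 12 genes with the largest difference among those past the threshold, in each list the 2 members with the smallest p (4 where the list passed), and PGR, ESR1, OXTR, PTGS2, IGF1, ISG15 and MX2 whatever their values; a gene with several probes is represented by its brightest, except in the first part of the rule. A gene named by this rule is not reported here, although counts include it. These tests, the lists, the naming rule and most of the other settings tried were fixed before the data were examined.

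Slide and scan day were read from the file headers: 6 slides and 4 days were known for 10 arrays, 0 slides and 0 days held both groups, and fertile cow 6 was given a slide and day of its own. Slide and day were therefore entered as random blocks (duplicateCorrelation, consensus correlation 0.447 and 0.314), with list tests by cameraPR on the moderated statistics. Other settings fixed beforehand were normexp background correction with an offset of 50, quantile normalization, median centring, the authors' value table, other filters on dim probes, leaving out each cow, slide, scan day and replicate number as blocks, array weights, a trended robust variance, the balance of epithelial and stromal markers as a covariate, other thresholds, and other choices for the list tests and detection flag. Trends with GC content and brightness were removed with natural splines of 4 and 5 degrees of freedom within each array.

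The steps were tested on simulated data made from the means and spread of the 31877 tested probes. Between 6 and 5 arrays limma recovered 56.0% of 100 probes changed 2-fold and 89.0% of 100 changed 4-fold, with 8 false calls among 153. The simulated noise was independent between probes and between arrays, without differences between slides or days. The false calls therefore do not bear on calls that such differences could make. In 50 simulations over 18431 genes without correlation between genes, camera recovered a list shifted by 0.5 in 100% of cases, with a mean of 0.06 false lists.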

Results

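Endometrial biopsies collected on day 7 of the oestrous cycle were profiled on 1-colour oligonucleotide microarrays, with 1 array for each cow. The fertile group held 6 cows that had conceived by embryo transfer or artificial insemination within 3 attempts and that conceived again at the transfer following the biopsy. The subfertile group held 5 cows with 3 failed attempts in a row, no abnormality found in the genital tract and cycles that appeared normal. The comparison asks how transcript levels in the endometrium differed between these groups at a fixed point of the cycle. Of 43653 probes, 31877 passed the filter on dim signal and were tested, and 24309 of these carried the symbol of 1 of 12015 genes. Differences are given throughout as subfertile minus fertile on the log2 scale, with n = 6 fertile and n = 5 subfertile cows, and the number of arrays limits their precision.

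The arrays of the groups differed in brightness. The median processed signal ranged from 161 to 452 on fertile arrays and from 54.3 to 92.7 on subfertile arrays, a mean log2 difference of -1.93 (exact two-sided permutation test, p = 0.00216, the smallest value the 462 splits can give). The share of probes well above background was 74.2% ± 1.88 (SD, n = 6) in fertile and 68.4% ± 3.54 (SD, n = 5) in subfertile cows, a difference of -5.75 percentage points (exact two-sided permutation test, p = 0.0130). No known slide and no known scan day held arrays of both groups: the subfertile arrays lay on 3 slides scanned on 1 day, the fertile arrays with a known slide lay on 3 other slides scanned on 3 other days, and the slide and day of fertile cow 6 were unknown. Values within a slide or day can therefore not be given for any difference between the groups. A call kept with slide or scan day as a random block is not thereby free of a difference between slides or days. The first principal component held 34.0% of the variance between arrays and placed every fertile cow on 1 side and every subfertile cow on the other.

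**Figure D1:**
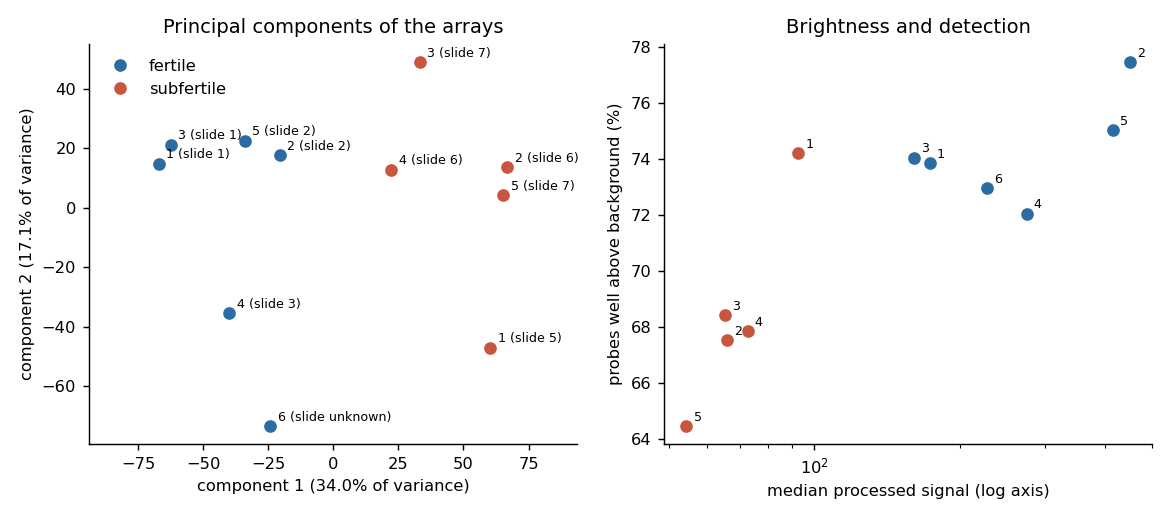
Left, the first and second principal components of the 11 arrays over tested probes, with the share of variance on each axis and each point marked by replicate number and slide. Right, the percent of probes well above background against the median processed signal on a log axis, numbered by replicate; the 5 subfertile arrays lie between 54.3 and 92.7 in median signal and the 6 fertile arrays between 161 and 452.

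Endometrium of subfertile cows had lower IGF1 signal, higher signal for the epithelial gene CLDN3, and higher signal for FOXJ1, the master transcription factor of motile cilia. Of these 3 genes only CLDN3 passed with scan day as a random block. Only FOXJ1 passed with the balance of epithelial and stromal markers as a covariate, which is made in part from CLDN3. IGF1, the insulin-like growth factor produced by uterine stroma, fell on all 3 of its probes, by 0.90 to 1.42 on the log2 scale (adjusted p = 0.00856 to 0.0350), and 2 of the 3 passed with slide as a random block. With scan day as a random block its adjusted p was 0.108 to 0.224. The call of its brightest probe was lost on leaving out any of 7 cows. With that covariate this probe was at -0.21 (adjusted p = 0.734) and CLDN3 at 0.59 (adjusted p = 0.101). Since CLDN3 is part of the covariate, this is no test of CLDN3. Every subfertile cow lay above every fertile cow in that balance, so the covariate cannot tell a change in makeup from a group difference for IGF1. Large rises included SPTSSB, a small subunit of serine palmitoyltransferase, FXYD2, a regulator of the sodium pump, and FGL1, a fibrinogen-like secreted protein. Large falls included CA1, a carbonic anhydrase, SFRP4, a secreted antagonist of WNT signalling, GRIK1, a kainate receptor subunit, and PENK, the enkephalin precursor. In total 7074 probes passed the limma test at an adjusted p below 0.05, 22.2% of those tested, with 4722 higher and 2352 lower in subfertile cows; the higher calls covered 2749 named genes and the lower calls 1439.

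The balance of higher and lower calls depended on the scaling. The median difference over all tested probes was 0.07 with each array set to its 75th percentile, where 66.8% of calls were higher, and -0.01 with quantile normalization, where 3243 probes were higher and 3146 lower. Centring on the median gave 3136 higher and 3449 lower. The groups did not overlap at 4315 of the 31877 tested probes, 13.5%, where chance gives 0.433%. With slide as a random block 3676 probes passed, all among the 7074, and with scan day as a random block 978 passed, again all among them. Leaving out subfertile cow 2 left 4525 calls.

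Among the genes with the largest rises, SPTSSB was higher by 2.57 ± 0.23 (SE), 5.93-fold, with adjusted p = 9.63e-05, and was well above background on 2 of 6 fertile and 5 of 5 subfertile arrays. FGL1 was higher by 2.92 ± 0.45 (adjusted p = 0.00182) on 1 of its 4 probes and was measured on 1 of 6 fertile arrays. FXYD2 was higher by 4.15 ± 0.70 (adjusted p = 0.00283) on 1 probe and by 2.58 on the other, measured on 1 of 6 fertile and 4 of 5 subfertile arrays. CHST4, a sulfotransferase that modifies surface glycans, was higher by 2.89 ± 0.62, and FOSB, an AP-1 subunit, by 2.55 ± 0.57; fertile slides 2 and 1 differed by 2.10 and 1.33 for these genes. PLA2G2F, a secreted phospholipase, had the largest difference, 4.38 ± 1.23 (adjusted p = 0.0270). Fertile cow 3 lay inside the subfertile range, and the call was lost on leaving out any of 7 cows and with slide as a random block (adjusted p = 0.0840). C3H1orf56, OAZ3, BEND3, ERF, LFNG and PHF12 were higher by 2.48 to 3.18, with no overlap between the groups. Within the fertile group these 6 genes likewise differed between slides, with slide 2 above slide 1 by 1.73 for LFNG up to 3.46 for ERF, 2 cows on each slide.

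Among the genes with the largest falls, REEP2 was lower by -3.75 ± 0.36 (adjusted p = 1.68e-04) on 1 probe and by -2.76 on another of its 3, and CATHL2, a cathelicidin, by -3.55 ± 0.35 (adjusted p = 1.75e-04) on 1 probe and by -1.49 on the other. The first probe of each was well above background on 1 of 5 subfertile arrays. GRIK1 was lower by -2.84 ± 0.33 (adjusted p = 4.21e-04) with all arrays well above background. CA1 was lower by -3.79 ± 0.82, NT5E, the ecto-nucleotidase that makes adenosine, by -3.61 ± 0.90, TEX29 by -3.40 ± 0.55, SFRP4 by -3.23 ± 0.69 and PYGO1, a WNT co-activator, by -2.62 ± 0.30, measured on 2, 3, 3, 1 and 2 of 5 subfertile arrays. PYGO1 passed on 1 of 3 probes. With normexp correction the calls of REEP2, CA1, NT5E, SFRP4 and PYGO1 were lost, at -0.43, -0.79, -1.03, -0.24 and -0.23. PENK was lower by -2.78 ± 0.89 (adjusted p = 0.0431), a call lost on leaving out any of 8 cows, and neither it nor NT5E passed with slide as a random block (adjusted p = 0.202 and 0.0560). BDA20, which encodes a bovine dander allergen, was not well above background on any subfertile array and was at least 2.49-fold lower, although with normexp background correction its difference was 0.37 (adjusted p = 0.434).

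CD4, IGF2 and FGF2 had probes that passed in opposite directions. The dim CD4 probe was not well above background in subfertile cows and was at least 4.34-fold lower there (adjusted p = 4.45e-04), although it was at -0.075 with normexp correction (adjusted p = 0.818). The brighter CD4 probe was higher by 1.45 ± 0.31 (adjusted p = 0.00775), where fertile slides 2 and 1 differed by 1.57. For IGF2, 1 of 13 probes was not well above background in subfertile cows and was at least 3.59-fold lower (adjusted p = 9.58e-05), although its difference was 0.09 with normexp correction; the other 12 were higher, 7 of them past the threshold, the brightest by 1.22 ± 0.22 (adjusted p = 0.00358). For FGF2 the brightest of 5 probes was higher by 0.58 ± 0.10 (adjusted p = 0.00354) and the other 4 were lower, 1 of them past the threshold at -0.55 (adjusted p = 0.0466). None of the 3 genes can be given a single direction from these arrays.

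**Figure D2:**
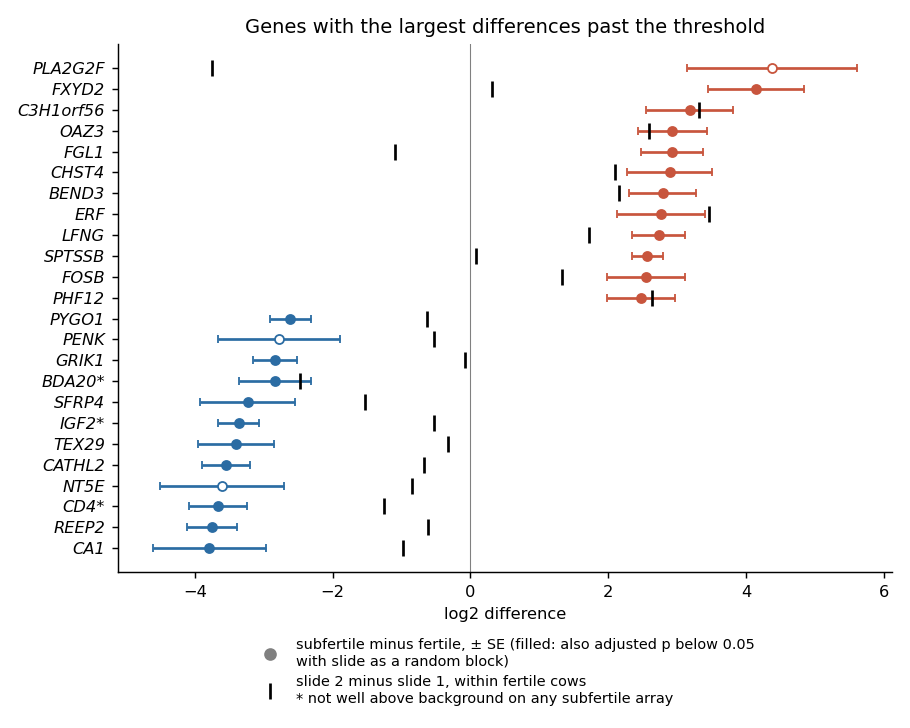
Log2 differences, subfertile minus fertile, of the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with SE bars and n = 6 and 5 cows; filled points also passed with slide as a random block. Black ticks give the difference between fertile slides 2 and 1, which for C3H1orf56, ERF and PHF12 is larger than the group difference.

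Epithelial and ciliated cell markers were higher and proliferation genes lower in subfertile cows, the 3 of 23 gene lists that passed with a preset correlation between genes. None of the 3 passed with an estimated correlation (unadjusted p = 0.150 for epithelial, 0.376 for ciliated and 0.277 for proliferation, adjusted p = 0.821 for each). Among 100 splits of the arrays into 6 and 5, 91 passed as many lists. Over all 18430 genes, tested with 1 probe per gene, 2639 were called higher and 1461 lower. Counts of calls within a list, here and below, are to be read against these. Of 24 tested epithelial markers 11 rose and none fell, 13 when adjusted over the list alone, with a median difference of 0.48 (camera, adjusted p = 0.00534). CLDN3, a tight junction protein, rose by 1.08 ± 0.18 (adjusted p = 0.00245), CDH1, the epithelial cadherin, by 0.61 ± 0.15 (adjusted p = 0.0170) on 1 of 3 probes and ELF3, an epithelial transcription factor, by 0.54 ± 0.15 (adjusted p = 0.0276). The calls of CDH1 and ELF3 were lost with slide as a random block (adjusted p = 0.0761 and 0.0977) and with trends with GC content and brightness removed (adjusted p = 0.0544 and 0.669), where the list median was 0.30. Of 21 ciliated cell markers 4 rose and none fell, all 21 were above 0, and the median was 0.75 (camera, adjusted p = 0.00968). The list mean was 0.04, 1.39, 0.32, -0.66 and 1.13 in subfertile cows 1 to 5, against -0.71 to -0.004 in fertile cows. Subfertile cow 4 thus lay within the fertile range. FOXJ1 rose by 1.90 ± 0.32 (adjusted p = 0.00273), CAPS by 1.32 ± 0.36, CCDC39 by 1.22 ± 0.36 and DNAAF11 by 0.98 ± 0.28, but only FOXJ1 of these passed with slide as a random block, and none with scan day (adjusted p = 0.0559 for FOXJ1). The proliferation list had a median of -0.54 (camera, adjusted p = 0.00483), although 2 of 27 genes fell and 25 did not pass. Fertile cow 4 stood at 1.16 for this list, the other fertile cows between -0.39 and 0.31. Without it the median was -0.29. CCNB1, the mitotic cyclin, fell by 0.53 ± 0.14 (adjusted p = 0.0233); CENPE, a kinetochore motor, was not well above background on any subfertile array and was at least 2.28-fold lower, although its difference was 0.47 with normexp correction. CCNA2 at -0.94 ± 0.36 and the brightest MCM3 probe at -0.70 ± 0.27 did not pass, while another MCM3 probe passed at -0.76 and its dimmest was at 0.46. The rotation test fry, which does not compare a list with other genes, passed epithelial markers and B and plasma cell markers (adjusted p = 0.0430 for each). The mean of epithelial minus stromal markers was -0.30 ± 0.36 (SD, n = 6) in fertile and 0.36 ± 0.26 (SD, n = 5) in subfertile cows, a difference of 0.65 (exact two-sided permutation test, p = 0.00433). With normexp correction none of the 3 lists passed, although the epithelial and ciliated genes named here did, and the proliferation median was 0.10, against 0.33 for all tested probes. Ciliated markers did not pass without subfertile cow 2 (adjusted p = 0.0819) or without subfertile cow 5, nor with slide as a random block (adjusted p = 0.0771).

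**Figure D3:**
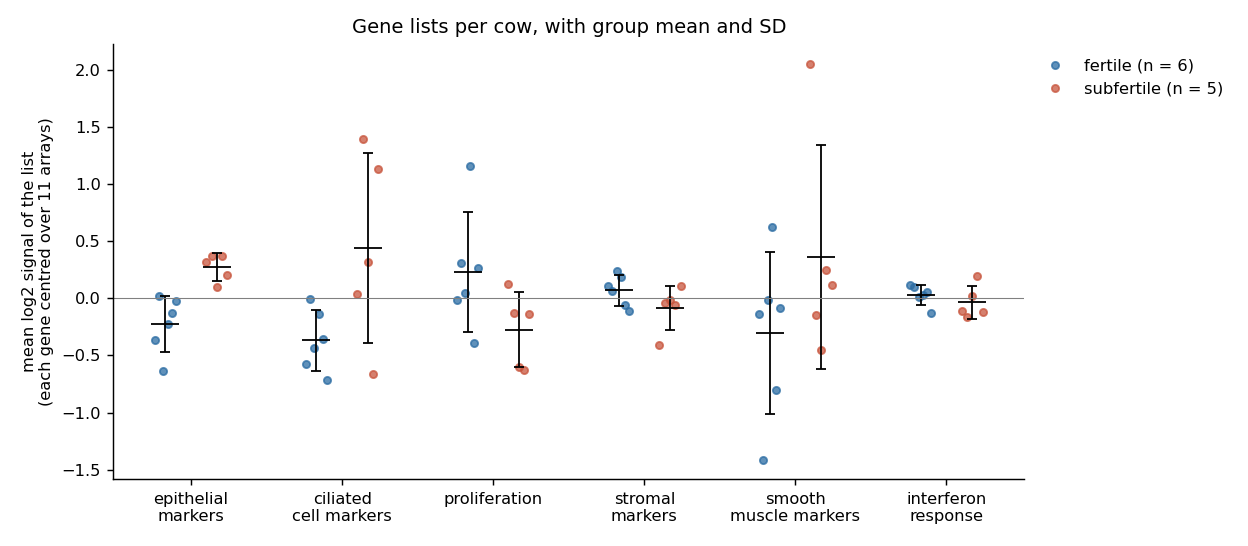
Mean log2 signal of 6 gene lists for each cow, each gene centred over the 11 arrays, with the mean and SD of each group in black. Epithelial marker values of all 5 subfertile cows lie above those of all 6 fertile cows, and subfertile cow 1 stands apart at 2.05 for smooth muscle markers.

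None of the lists of other cell types passed. Of 17 stromal markers 3 rose and 2 fell, and the list did not pass (median -0.16, adjusted p = 0.294); the microfibril gene FBN1 fell by 0.98 ± 0.20 and FN1, fibronectin, fell by 0.80 ± 0.17 on its brightest probe, with 6 of its 13 probes past the threshold. The stromal list passed with quantile normalization (median -0.34) and with trends removed (median -0.30). Of 16 endothelial markers 4 rose (median 0.24, adjusted p = 0.296), among them PLVAP by 0.79 ± 0.17 and TIE1 by 0.90 ± 0.22. Of 14 smooth muscle markers 2 rose, 1 when adjusted over the list alone (median 0.73, or 0.32 without subfertile cow 1, adjusted p = 0.186): SMTN was higher by 0.89 ± 0.21 on its brightest of 3 probes, all of which passed, and LMOD1 by 0.73 ± 0.23. Of 14 macrophage markers 1 fell, 0 when adjusted over the list alone (median -0.21, adjusted p = 0.208; without fertile cow 6, -0.38 and adjusted p = 0.0168; without subfertile cow 1, -0.072 and adjusted p = 0.506): VSIG4 at -0.999 ± 0.32, a call lost with normexp correction, with MRC1 at -1.02 ± 0.39 not past the threshold. Of 11 B and plasma cell markers 2 rose (median 0.51, adjusted p = 0.184), CD79A by 1.43 ± 0.25 and FCER2 by 0.51 ± 0.14. Of 21 T and NK cell markers 2 rose (median 0.02, adjusted p = 0.546), PRF1, perforin, by 0.94 ± 0.23 and the brighter CD4 probe. Neutrophil markers had 1 rise and 1 fall among 9 (adjusted p = 0.896), ELANE, neutrophil elastase, at 1.47 ± 0.27 and CATHL2. Erythroid markers had 1 rise and 2 falls among 7 (adjusted p = 0.522): SLC4A1 was higher by 1.31 ± 0.32, measured on 3 of 6 fertile and 4 of 5 subfertile arrays, and EPB42 was not well above background in subfertile cows and was at least 1.61-fold lower, although its difference was 0.67 with normexp correction.

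Genes of receptivity and hormone response moved in both directions. Of 12 steroid and oxytocin receptors and cochaperones 1 rose and 1 fell, 2 falling when adjusted over the list alone (median -0.13, adjusted p = 0.296): ESR2, the beta oestrogen receptor, fell by 0.86 ± 0.16 (adjusted p = 0.00473) on 1 of 3 probes. FKBP4, a progesterone receptor cochaperone, rose by 0.65 ± 0.21, where fertile slides 2 and 1 differed by 0.69. The progesterone receptor PGR was at 0.23 ± 0.17 (adjusted p = 0.345) and the oxytocin receptor OXTR at -0.58 ± 0.47 (adjusted p = 0.398), neither past the threshold. ESR1, the alpha oestrogen receptor, was at 0.44 ± 0.27 (adjusted p = 0.265) on its brightest probe, with 1 of 4 probes past the threshold. PTGS2, the inducible prostaglandin synthase, was at -0.67 ± 0.48 (adjusted p = 0.335). In the prostaglandin list 1 of 18 genes rose and 2 fell (adjusted p = 0.896): AKR1B1, an aldose reductase with prostaglandin F synthase activity, was higher by 0.75 ± 0.14 but at -0.085 with quantile normalization, and AKR1C4 was at -1.38 ± 0.41. Of 27 growth factors and receptors 3 rose and 3 fell (adjusted p = 0.546), with the brightest FGF2 and IGF2 probes among the rises and other probes of both passing as falls. Of 31 histotroph and transport genes 5 rose and 3 fell (median 0.00, adjusted p = 0.546): NID2, a basement membrane nidogen, fell by 0.79 ± 0.11 (adjusted p = 9.92e-04) on both probes and passed with slide and with scan day as a random block (adjusted p = 0.00494 and 0.0287), and LGALS9, a galectin, rose by 0.80 ± 0.16. Of 24 WNT and patterning genes 3 rose and 3 fell (adjusted p = 0.546), with AXIN2, a feedback target of WNT signalling, higher by 1.02 ± 0.18 on the brighter of 2 probes, both of which passed, and WNT5A by 1.97 ± 0.40 on 1 of 2 probes, where fertile slides 2 and 1 differed by 2.05.

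Immune and stress genes varied within their lists. Of 36 interferon response genes 3 rose and 2 fell (median -0.04, adjusted p = 0.546): RSAD2, an antiviral enzyme, fell by 0.73 ± 0.16, a call lost with normexp correction at -0.17, and XAF1 rose by 0.74 ± 0.20, where fertile slides 2 and 1 differed by 0.85, while ISG15 at -0.04 ± 0.29 and MX2 at 0.29 ± 0.28, well above background on 2 of 5 subfertile arrays, did not pass. Of 22 innate inflammation genes 4 rose (median 0.24, or 0.14 without subfertile cow 5, adjusted p = 0.526), with IL10, an anti-inflammatory cytokine, higher by 0.97 ± 0.19 and TLR2, a toll-like receptor, by 0.43 ± 0.10, the latter at -0.081 once trends with GC content and brightness were removed. Of 18 antigen presentation genes 4 rose and 1 fell (adjusted p = 0.501): CD74, the class II invariant chain, was higher by 0.80 ± 0.16, and B2M by 0.70 ± 0.15 on 1 of 4 probes but at -0.03 with quantile normalization. Of 17 complement genes 2 rose (adjusted p = 0.962): CD59 by 0.73 ± 0.14, and CLU, clusterin, by 0.60 ± 0.14 but at -0.10 with quantile normalization. Of 21 immediate-early and heat-shock genes 4 rose (median 0.55, adjusted p = 0.160), among them HSPB1 by 0.70 ± 0.13 and FOSB. Without subfertile cow 5, which stood at 1.64, the list median was 0.10. Of 28 matrix remodelling genes 1 rose and 3 fell (median -0.12, adjusted p = 0.184; with trends removed, -0.36 and adjusted p = 0.00938), with the gelatinase MMP2 lower by -0.66 ± 0.13 on 1 of 5 probes and MMP19 by -0.95 ± 0.24. Of 8 mucins and surface glycoproteins 1 rose, 0 when adjusted over the list alone (adjusted p = 0.651): FUT2, a fucosyltransferase, at 1.33 ± 0.42, with TFF3 at 0.57 ± 0.25 not past the threshold. In every list whose count adjusted over the list alone is not given, it equalled the count over all probes. Median and mean differed in sign in the erythroid, neutrophil and prostaglandin lists (medians 0.09, 0.18 and 0.16, means -0.05, -0.16 and -0.08, test direction down), and the test pointed down although both were above 0 for T and NK cell markers and complement. With CENPE and EPB42 at their bounds the medians of their lists are the same, and the erythroid mean is 0.17, of the same sign as its median. Leaving out fertile cow 6 brought the macrophage, matrix remodelling and immediate-early lists past the threshold, leaving out subfertile cow 1 the B and plasma cell, antigen presentation and immediate-early lists, and leaving out subfertile cow 4 the immediate-early and macrophage lists.

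Among the 71 named calls, 50 passed with slide as a random block. The other 21 were those of PLA2G2F, NT5E, PENK, CCNB1, CDH1, ELF3, CAPS, DNAAF11, CCDC39, MMP19, LMOD1, VSIG4, FKBP4, B2M, TLR2, RSAD2, XAF1, PRF1, FUT2, AKR1C4 and the brightest IGF1 probe. Leaving out single cows ended the calls of 14, namely PLA2G2F, PENK, CCNB1, ELF3, CAPS, DNAAF11, CCDC39, FCER2, LMOD1, VSIG4, FKBP4, FUT2, AKR1C4 and the brightest IGF1 probe. With scan day as a random block 19 named calls passed, those of C3H1orf56, OAZ3, FGL1, BEND3, LFNG, SPTSSB, PHF12, REEP2, CATHL2, BDA20, GRIK1, PYGO1, CLDN3, CD79A, EPB42, NID2, WNT5A and the dim CD4 and IGF2 probes. All subfertile arrays shared a scan day, so passing here does not exclude a difference between days. C3H1orf56 and PHF12 passed although fertile slides 2 and 1 differed by 3.31 and 2.64, more than their group differences of 3.18 and 2.48. The gap between these slides also exceeded the group difference for WNT5A, which passed. With the balance of epithelial and stromal markers as a covariate 19 passed, those of PLA2G2F, FXYD2, FGL1, SPTSSB, REEP2, CATHL2, GRIK1, PYGO1, CCNB1, FOXJ1, HSPB1, TIE1, ESR2, EPB42, TLR2, NID2, CD59 and the dim CD4 and IGF2 probes. With trends removed PENK, CDH1, ELF3, CCDC39, HSPB1, FCER2, CD74, B2M, LGALS9, PRF1, FUT2, AKR1B1 and the brightest FGF2 probe kept their direction and did not pass, with LGALS9 at 0.33, CD74 at 0.49, PRF1 at 0.57 and FCER2 at 0.16. PENK at -2.73 and CCDC39 at 1.13 stayed near their differences of -2.78 and 1.22. Fertile slides 2 and 1 differed in the direction of the group difference by more than 0.5 of it for C3H1orf56, OAZ3, BEND3, ERF, LFNG, PHF12, CHST4, FOSB, BDA20, CLDN3, CAPS, DNAAF11, CCDC39, CD79A, FCER2, FKBP4, SLC4A1, IL10, XAF1, WNT5A, ELANE and the brightest CD4 and IGF1 probes. With quantile normalization ELF3, HSPB1, LMOD1, FUT2, TLR2 and the brightest IGF2 probe kept their direction and did not pass. Of the named genes past the threshold with several tested probes, a number passed on only 1 of them. These included FGL1, ERF, FOSB, PHF12, CCNB1, MMP19, LMOD1, VSIG4, TLR2, XAF1, LGALS9, PRF1 and AKR1C4. PYGO1, CDH1, MMP2, ESR2, B2M and WNT5A, described above, did so too.

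The group difference followed the GC content and the brightness of the probe. The median difference rose from -0.12 over 6276 probes with at most 35% GC to 0.58 over 258 probes above 60% GC, and was 0.49 over the 757 probes with a mean log2 signal of 15 or more. Quantile normalization removed the second trend (-0.03) and kept the first (-0.19 and 0.52). With both trends removed within each array, 4805 probes passed, 2497 higher and 2308 lower, and 3691 of the 7074 calls were among them with the same sign.

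**Figure D4:**
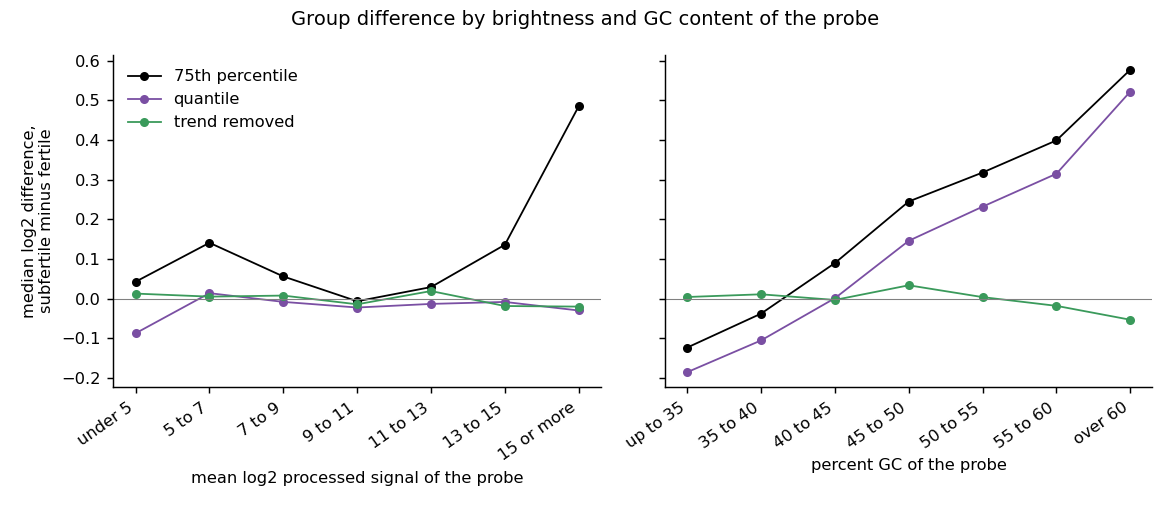
Median log2 difference, subfertile minus fertile, over tested probes grouped by mean log2 signal (left) and by percent GC of the probe (right), for 3 ways of scaling. With the 75th percentile the median reaches 0.49 for the brightest probes and 0.58 above 60% GC.

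Cows of the 2 groups were about equally far from their own group. The mean root mean square log2 distance of an array to the centre of the other arrays of its group was 0.46 in fertile and 0.49 in subfertile cows, a difference of 0.03 (exact two-sided permutation test, p = 0.515). The other splits mix the groups and so carry the difference between them, and this p does not measure the spread alone. The subfertile arrays shared a scan day and the fertile arrays did not, so the fertile distance also holds any difference between days.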

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

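The tests of slides, of trends with GC content and brightness and of other probes of a gene were chosen only after the results were seen; the splits of the arrays and the tissue makeup covariate were set before.

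Of 216 groups of values checked for a single cow far from the others, 17 were marked, where chance marks about 1 in 20. Fertile cow 3 had the highest fertile PLA2G2F value at -0.060, the others lying between -6.55 and -4.64, and subfertile cow 4 the lowest subfertile one at -4.20. Subfertile cow 4 was highest in its group for SFRP4 at -3.70 and GRIK1 at -1.39. Subfertile cow 1 was highest in its group for the dim CD4 probe at -5.93, CATHL2 at -4.86, CCNA2 at -4.27, SMTN at 3.55 and the smooth muscle list at 2.05, where the others lay between -0.45 and 0.25, and lowest for TLR2 at 5.48. Subfertile cow 3 was lowest for FUT2 at -3.86, and fertile cow 5 highest for MX2 at -4.72. For list means, fertile cow 3 was lowest in antigen presentation at -0.61, subfertile cow 5 highest in innate inflammation at 0.81, fertile cow 2 lowest in neutrophil markers at -0.61, and fertile cow 6 lowest in macrophage markers at -0.84 and in WNT and patterning genes at -0.44.

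The 7074 probes that differed between the groups. Of 100 splits of the arrays into 6 and 5, only the real 1 gave as many, and the highest other gave 670. The real split thus stood apart from the others drawn. It also separates the known slides and scan days, so the count cannot show that the difference follows fertility. Removing the trends with GC content and brightness left 3691 of the calls with the same sign; with them removed 4805 probes passed in the real split and at most 816 in the other 99, which argues against those trends as the whole cause. Slide and scan day cannot be told apart from the group, since no known slide or day held both: with scan day as a random block 978 calls were kept. Fertility, labelling or hybridisation on different days, and array brightness all stay open.

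The probes that differed by at least 4-fold. Over the 99 such probes that were higher in subfertile cows (median 2.30), slide 2 exceeded slide 1 within the fertile group by a median of 1.56. Cows of the same slide differed by a median of 0.21. Fertile slides 1 and 2 were also scanned on different days, so this gap cannot tell slide from day. A difference between slides or days may account for much of this set. Over the 75 that were lower (median -2.38) the same gap was -0.52, with quartiles of -0.96 and -0.17. A difference between slides or days cannot be told apart there because of its spread. Where such genes had other tested probes, those moved by a median of 0.75 for 28 higher and -1.003 for 30 lower probes, well short of the original differences but in the same direction, so a response of single probes can be neither excluded nor shown. A difference in fertility stays open for both sets, untested apart from the slides and days.

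The 3 gene lists past the threshold. As many lists passed in 91 of 100 splits of the arrays, the highest other giving 10, so chance assignment of cows is not excluded for the count of lists. The estimated correlation between genes was 0.22 to 0.67 in these 3 lists, against the preset 0.01. Whether this or structure among the arrays made so many splits pass was not tested. Removing the trends with GC content and brightness left the mean of the proliferation list at -0.52 (from -0.50) and of the ciliated list at 0.68 (from 0.81), which argues against those trends as the cause of these lists. The epithelial mean moved from 0.50 to 0.28 (list adjusted p = 0.0427), so the trends may carry part of it but not the whole. With the balance of epithelial and stromal markers as a covariate the ciliated mean was 1.03 ± 0.56 (SE), against 0.81 ± 0.36 without it. The proliferation mean was -0.59 ± 0.43, against -0.50 ± 0.27 without it. Every subfertile cow lay above every fertile cow in that balance, and the errors grew with it in the fit. The covariate therefore cannot tell either list's difference apart from a change in makeup, which stays open for both. The group's fertility and the share of ciliated cells in a biopsy stay open, untested.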

How the results depend on the processing

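Removal of GC and brightness trends, quantile normalization with a slide block, leaving out pairs of arrays and permutation of list means were chosen after seeing the data. The 7074 calls became 17090 with normexp correction (14931 higher), whose offset is close to the signal of the dimmer subfertile arrays, 12198 with no filter on dim probes (median of all probes 0.17), 3676 with slide and 978 with scan day as a random block, 3038 with quantile normalization and slide, 1735 with the tissue makeup covariate, 1589 at unadjusted p below 0.05 with at least 2-fold and 4100 with 1 probe per gene; apart from the threshold and the number of probes, the cause was not tested. Leaving out each cow gave 4525 to 7316, the lowest without subfertile cow 2. Without fertile cows 1 and 6, whose files are in doubt, 4792 probes passed. At least 50.8% of calls were higher in every fit except median centring, at 47.6%.

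The 3 lists became 1 with normexp correction (a different list, matrix remodelling), 1 with no filter, 5 with the trends removed, 6 without fertile cows 1 and 6, 0 with an estimated correlation and 0 by exact permutation of list means (smallest adjusted p = 0.0996). Leaving out each cow gave 2 to 6. The replicate block, fitted without fertile cow 6, gave 6, as did leaving out that cow alone. The cause was not tested. Without fertile cows 4 and 6, whose spike-in signals were low, the proliferation list did not pass (adjusted p = 0.0579). The spread within groups passed in no alternative, and the share of probes detected passed in all, from -7.18 to -4.74 without single cows.

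Directions turned with normexp correction for the proliferation median (0.10), the dim IGF2 probe (0.088), BDA20 (0.37), CENPE (0.47) and EPB42 (0.67), and with quantile normalization for B2M (-0.029), AKR1B1 (-0.085) and CLU (-0.096), or -0.037, -0.073 and -0.091 with slide added. With trends removed TLR2 was at -0.081 and CLU at -0.29. The normexp offset lifts dim probes more on the dimmer subfertile arrays after scaling. Turns of dim probes with normexp therefore cannot decide their direction. Signs that turned where neither value passed are not counted. Of 71 named calls, 50 were kept with slide and 19 with scan day as a random block, 19 with the tissue makeup covariate, and 57 when any 1 cow was left out. FGL1, SPTSSB, CATHL2, GRIK1 and NID2 passed in every setting in which they were tested.

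The replicate numbers belong to different animals, and correlations of same-numbered deviations ran from -0.15 to 0.18, with 2 of 5 fertile cows closest to their own number, so the numbers share only a label. With the replicate block, fitted without fertile cow 6, 4761 probes passed, against 7316 without that cow and with no block. Signal over background limits the falls: 113 called probes were not well above background on any subfertile array, against 4 on any fertile array.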

Other observations

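The genes and families in this part were chosen after their values were seen.

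Several genes differed on all of their probes. Of 7186 named genes with at least 2 tested probes, 3051 had at least 1 probe past the threshold. Of these 3051, 409 (13.4%) had every probe past it in 1 direction, 299 higher and 110 lower in subfertile cows. Of the 409, 92 also passed on at least 2 probes with slide as a random block, with quantile normalization and with trends removed. EZH2, the histone methyltransferase of the polycomb repressive complex, was lower on all 6 probes, from -1.25 to -0.95. The sodium pump subunit ATP1B3 was lower on 4 of 4 probes (median -0.93), the angiogenic factor VEGFA on 3 of 3 (median -0.66) and SPC24, a kinetochore protein, on 2 of 2 (median -1.96). The stress chaperone HSPA1A was higher on 5 of 5 probes (median 1.18), the clock gene PER1 on 5 of 5 (median 0.80), TMSB4X, an actin-binding thymosin, on 3 of 3 (median 1.57), the receptor ERBB3 on 3 of 3 (median 1.25) and SGK1, a steroid-induced kinase, on 2 of 2 (median 1.24). With scan day as a random block all 3 TMSB4X probes, 3 of the ATP1B3, 3 of the HSPA1A and 2 of the PER1 probes passed, and 0 of the EZH2, VEGFA, SPC24, SGK1 and ERBB3 probes. In contrast, 302 genes had probes that disagreed in sign at an unadjusted p below 0.05.

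Keratins were higher on 11 of 31 probes and lower on 0, with a median of 0.75; 4 were higher with slide as a random block, and the median was 0.65 with quantile normalization and 0.48 with trends removed. Ribosomal protein probes were higher on 178 of 290, with a median of 0.54, but the median was -0.02 with quantile normalization, where 32 were higher and 20 lower. Collagens had a median of -0.04, with 9 probes higher and 13 lower, and -0.21 with quantile normalization.

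The spike-in RNA, not used in the comparisons, separated arrays within the fertile group. The brightest spike-in probe was at 3.07 and 3.01 on the log2 scale in fertile cows 4 and 6, against 6.19 to 7.16 in the other fertile and 6.73 to 7.64 in the subfertile cows. The dim spike-in probe E1A_r60_a104 was at -9.01 to -8.33 in fertile and -8.31 to -7.34 in subfertile cows. For E1A_r60_3, also dim, these ranges were -8.88 to -8.03 and -8.22 to -7.46. Dim spike-in signal thus tended to lie higher on subfertile arrays after scaling, and its bearing on dim probes was not tested. Across probes within arrays, which are not independent replicates, the median correlation was 0.989 for the 2 pairs of fertile cows on the same slide, 0.982 for the 8 pairs on different slides, 0.975 for the 5 pairs with fertile cow 6 and 0.969 for the 30 pairs of a fertile with a subfertile cow. Among subfertile cows it was 0.982 on the same slide and 0.977 on different slides.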
